A study of Mus musculus with 2 samples.

How the data were processed

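The data are 2 Affymetrix expression arrays of mouse uterine epithelial cells, 1 from floxed control mice and 1 from Msx1Msx2-null mice, both on day 4 of pregnancy. Per the labels' protocols, uterine pieces were incubated in 1% trypsin for 90 min, the epithelium was squeezed out with forceps, and 100 ng of total RNA was amplified with a 3' kit and labelled with biotin. The labels conflict on the sample: the treatment and design texts give epithelial cells from 5 mice per genotype lysed in Trizol, whereas the extraction text gives stromal cells from 4 per genotype and a Qiagen kit. The cell type field says epithelial, and that is followed here. Some markers of epithelium and some of stroma were bright on both arrays, as given below, so the signals do not show a pure epithelium. Whether RNA from several mice was pooled on an array is not stated.

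The deposited values are signal intensities on a linear scale, made with MAS5 in Affymetrix Expression Console version 1, per the submitters' processing notes. MAS5 subtracts a mismatch-based background and scales each array; the deposited intensities had a 2% trimmed mean of 150.001 on both arrays. Such scaling hides any difference in total RNA per cell, and MAS5 log ratios of dim probe sets are noisy. Values were used as deposited, without detection calls. Probe sets were named from the platform annotation: of 35890 listed, 34958 had 1 gene and 932 several. In all, 34754 matched a gene in the RefSeq table of assembly GRCm38.p6, and no symbol needed updating. Probe sets with several genes, and those not listed, were left unnamed (10092 of 45037 non-control probe sets, beside 64 control probe sets). The labels name no genome build for the probe sets, so no coordinates are given.

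Signals were taken to log2. The floor was the 50th percentile of non-control signals over both arrays, 21.1, and values below it were set to it. A gene took the probe set with the highest mean log2 signal among those naming that gene alone. Of 18193 genes, 10529 were at or above the floor on both arrays, 732 on the null array only, 401 on the control array only and 6531 on neither; the last were not compared. A fold against an array below the floor was calculated against the floor and is given as "at least". Differences are null minus control, and the threshold was 2-fold.

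With 1 array per genotype no test was possible, and the number of arrays limits the precision. The standard deviation of the log2 differences of probe sets of the same gene served as a gauge of measurement error. It was 0.42, 0.39 and 0.34 in the low, middle and high ranges of signal (1549, 1547 and 1549 genes). In a simulation of 10930 genes with noise of standard deviation 0.5, 98% of genes planted 4-fold higher and 82% of those planted 4-fold lower passed the threshold, as did 66% and 56% of those planted 2.5-fold higher and lower and 4.21% of unchanged genes. The noise level was chosen, not estimated from these arrays, and was the same at all signals. These shares follow from that choice and are not error rates of the real comparison. The simulated genes were all at or above the floor on the control array. Planted losses could therefore be cut short by the floor, whereas planted gains started above it. The lower detection of losses comes with that choice of genes and does not carry over to the counts of higher and lower genes. A list of 20 genes shifted by 0.6 reached the 100th percentile, and 4.5% of 200 unshifted lists lay outside the central 95%.

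Before the data were examined, 31 gene lists and 12 cell type marker lists were fixed (787 gene names, 729 with a probe set), along with the settings, their alternatives and the rule for naming genes. The lists follow textbook knowledge of the uterus, the labels and published themes of work on Msx genes, so those on Wnt signalling follow the labels' own wording. Each list's median difference was placed among those of 10000 random lists of the same size, matched on mean signal in 20 bins; percentiles describe these 2 arrays and are not tests. Members below the floor on 1 array entered at their bound. The naming rule took Msx1 and Msx2, then the 12 genes with the largest difference in each direction above the floor on both arrays, provided that every other measured probe set had the same direction. It added up to 5 bounded genes per direction and up to 4 members of each list with the largest difference measured on both arrays. Clone and model numbers were counted but not named, and genes outside the rule are said to have been chosen after their values were seen.

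Alternatives were other scalings (array medians, quantile normalization, loess with a span of 0.3), floors at the 33rd and 67th percentile, no floor with a pseudocount of 16, and the median over a gene's probe sets. Others were the omission of probe sets with shared or alternative sequence, thresholds of 1.5-fold and 3-fold, members above the floor on both arrays alone, and the mean in place of the median. Scaling to the hybridization controls was added after the data were seen. Work was done in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.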

Results

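Gene expression was measured in epithelial cells separated from the uterus of C57BL/6 mice on day 4 of pregnancy, the day on which the mouse uterus becomes receptive to the blastocyst. Msx1 and Msx2, a pair of homeobox transcription factors, had been ablated together with a Cre recombinase driven from the progesterone receptor locus, which acts in cells that express that receptor. The comparison asks how the uterine epithelium differs when both genes are lost, and the labels name Wnt signals and communication between stroma and epithelium as themes. There was 1 array for floxed control mice and 1 array for Msx1Msx2-null mice, each reporting 45101 probe sets, so no difference has a replicate check and no p-value was calculated. At or above the signal floor of 21.1 lay 50.4% of the non-control probe sets on the control array and 49.6% on the null array. The log2 signals of the 20653 probe sets above the floor on both arrays correlated across probe sets with r = 0.93, where probe sets are not independent replicates. The ratio of 3' to 5' probe set signal, a sign of RNA integrity, was 1.62 and 1.56 for Actb and 0.809 and 0.842 for Gapdh on the control and null arrays.

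The targeted genes came first. Msx1 was 82.1-fold lower in the null by its brighter probe set, with a signal of 3474 in the control and 42.3 in the null (log2 difference -6.36). The second Msx1 probe set was 59.0-fold lower, at 1658 and 28.1. Msx2 was far dimmer: 1 probe set read 63.4 in the control and 23.6 in the null, 2.69-fold lower (log2 -1.43), and the other lay below the floor on both arrays. The labels do not say which exons were removed, so these probe sets check the labels only if they lie in or depend on the deleted part. With the floor raised to the 67th percentile, Msx2 was below it on both arrays and had no difference.

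With 1 probe set per gene, more genes were higher than lower in the null sample. Of 11662 genes measured on at least 1 array, 902 (7.73%) were at least 2-fold higher in the null and 554 (4.75%) at least 2-fold lower, so 62.0% of these genes were higher. The only gauge of error was the disagreement between probe sets of the same gene, with a standard deviation of 0.38 on the log2 scale (4645 genes, 12290 probe sets), which holds no spread between animals. Where a gene had a further measured probe set, all of them pointed the same way for 211 of 221 higher genes (95.5%) and for 200 of 213 lower genes (93.9%). All further probe sets also reached 2-fold for 110 higher genes (49.8%) and 97 lower genes (45.5%). The balance depended on which scaling was used. Under the planned scalings higher genes made up 64.8% with array medians and 65.1% with quantile normalization and with loess. With the arrays set to their hybridization spike-in controls, a choice added after the data were seen, 593 genes were higher and 1001 lower. Higher genes then made up 37.2%, and the median difference of all genes moved from 0.07 to -0.19. The unit counted mattered as well. Of 18185 named probe sets above the floor on both arrays, 5.70% were at least 2-fold higher and 6.38% lower. With the median over a gene's probe sets, 806 genes were higher and 517 lower.

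Among genes above the floor on both arrays whose probe sets agreed in direction, the 12 with the largest excess in the null are described one by one and share no tested theme; some genes with only a bound, given further below, exceed them. Id3, an inhibitor of basic helix-loop-helix transcription factors and a classic target of BMP signalling, was 21.6-fold higher (246 in the control, 5301 in the null, log2 4.43). Wfdc15b, of the whey acidic protein family, was higher by 4.32 on the log2 scale, and Cldn1, which encodes a tight junction claudin, 14.3-fold higher, with its 2 probe sets at 3.24 and 3.83. Fzd4, a Frizzled receptor for Wnt ligands, was 17.0-fold higher from a control signal of 25.3, close to the floor, and Crabp2, which carries retinoic acid in the cell, was 14.2-fold higher from 22.5. Igkv8-30, a kappa variable segment whose probe set can cross-hybridise with related segments, was 15.9-fold higher and Jchain, which links antibody polymers, 13.7-fold higher. Col5a2, a fibrillar collagen chain, was 13.1-fold higher, with probe sets at 2.93 and 3.71, and Egflam 15.3-fold higher. The others were Fam107a (20.6-fold), Hacd1, a dehydratase of fatty acid elongation (17.5-fold), and Uox, urate oxidase (14.3-fold). On this pair of arrays the marker lists of stroma, smooth muscle and macrophages had median log2 differences of 0.72, 1.38 and 0.93.

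Several genes crossed the floor upwards, so that only a bound can be given. The beta-defensins Defb6 and Defb3, antimicrobial peptides of epithelia, were at least 88.4-fold and at least 41.6-fold higher, with null signals of 1867 and 879. B4galnt2, a glycosyltransferase, was at least 31.2-fold higher by its brightest probe set, but with the median over its probe sets its log2 difference was 1.69 in place of 4.97. Clic6, of the intracellular chloride channel family, was at least 22.1-fold higher, with another probe set at 2.75. Gsta3, a glutathione S-transferase, was at least 20.8-fold higher by its brightest probe set, but a further probe set gave only 0.64 on the log2 scale. These bounds depend on the floor: at the 67th percentile their log2 values were 4.68 for Defb6, 3.60 for Defb3, 3.18 for B4galnt2, 2.68 for Clic6 and 2.60 for Gsta3, in place of 6.47, 5.38, 4.97, 4.46 and 4.38.

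After Msx1, the named gene with the largest deficit measured on both arrays was Etv5, an ETS transcription factor induced by FGF signals, 14.5-fold lower (797 in the control, 55.1 in the null, log2 -3.85). Ror2, a receptor for Wnt5a, was 12.6-fold lower and reached only 22.2 in the null, just above the floor, while Lgr5, the R-spondin receptor that marks many epithelial stem cells, was 8.07-fold lower. The anion exchanger Slc26a6 was 10.8-fold lower, the cyclic nucleotide phosphodiesterase Pde3b 10.3-fold lower and Ggt6, of the gamma-glutamyltransferase family, 8.59-fold lower. The orphan nuclear receptor Nr4a3 was 9.32-fold lower, Pstpip2 10.5-fold lower, Ankrd29 8.89-fold lower (probe sets at -3.15 and -2.02) and Arhgef26 8.60-fold lower. Prss23, a serine protease, was 11.4-fold lower by its brightest probe set, but its 3 probe sets ran from -3.51 to -1.31, so its size is uncertain. With the 67th percentile floor the folds of dim genes were smaller by a factor of more than 1.5, with log2 differences of 2.57 for Fzd4, 2.14 for Crabp2, 2.99 for Igkv8-30, -1.94 for Ror2, -2.10 for Slc26a6, -2.02 for Pstpip2 and -2.05 for Lgr5.

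Genes below the floor in the null included Slc22a4, an organic cation transporter (at least 10.9-fold lower), Sdr16c6 (at least 7.95-fold), Catsperz (log2 bound -2.91), Spink1, a trypsin inhibitor (at least 6.69-fold), and Cpsf4l (at least 10.5-fold). With the 67th percentile floor the log2 bounds were -1.67 for Slc22a4, -1.21 for Sdr16c6, -1.12 for Catsperz, -1.60 for Cpsf4l and -0.96, short of 2-fold, for Spink1. Without probe sets of shared or alternative sequence that of Cpsf4l was -0.35.

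**Figure D1:**
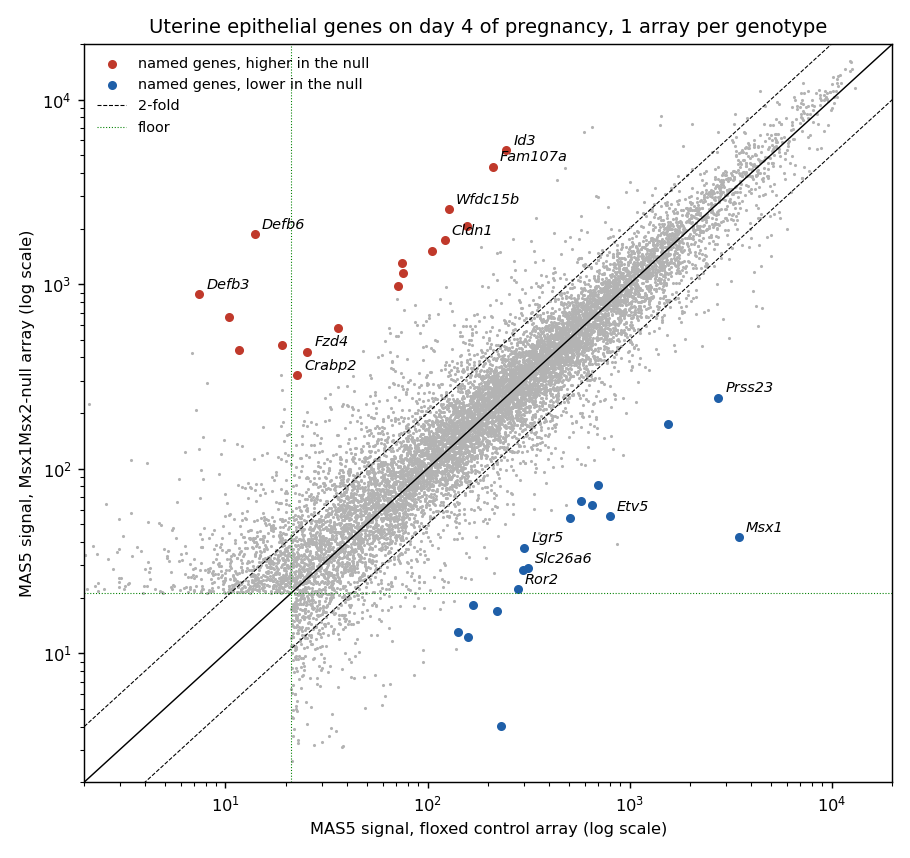
MAS5 signal of each measured gene on the control array (x axis, log scale) against the null array (y axis, log scale), with 1 array per genotype; grey points are genes, coloured points the named genes, dashed lines 2-fold and dotted lines the floor of 21.1. Msx1 lies farthest below the diagonal (3474 and 42.3), while Id3 (246 and 5301) and the beta-defensins Defb6 and Defb3 lie far above it.

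Genes of cell division were higher in the null sample as a group. Of 24 measured genes of the G2/M and mitosis list, 23 were at least 2-fold higher and none at least 2-fold lower. Their median log2 difference was 2.14 (4.41-fold), and 1.55 with the 67th percentile floor. Cenpa, the centromeric histone, was 8.38-fold higher, the mitotic kinesin Kif20a 8.01-fold, Birc5, a chromosomal passenger protein, 7.38-fold and the cyclin Ccna2 7.25-fold. The proliferation marker Mki67, chosen after its value was seen, was 2.86-fold higher. Top2a, the exception, also chosen after its values were seen, had log2 differences of 0.24 and 0.07. The median exceeded all 10000 random lists matched on signal, whose central 95% ran from -0.18 to 0.36, in this and all other settings tried. The S phase and DNA replication list lay above that range as well, with a smaller median of 0.61: 5 of 23 genes were at least 2-fold higher, among them the ribonucleotide reductase subunit Rrm2 (4.90-fold), Uhrf1 (3.82-fold), Rfc3 (2.56-fold) and cyclin E1, Ccne1 (2.41-fold). In the list of CDK inhibitors and D cyclins (14 measured, 4 higher, 2 lower, median 0.17) members went both ways: Rb1, which restrains entry into S phase, was 3.93-fold lower and the CDK inhibitor Cdkn1c 3.27-fold lower, while the CDK inhibitor Cdkn2c was 3.78-fold and cyclin D1, Ccnd1, 2.51-fold higher. Markers of macrophages, smooth muscle and stroma were higher on the same array, with medians of 0.93, 1.38 and 0.72.

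Oestrogen-responsive genes of the epithelium were higher in the null, and the progesterone-responsive list was slightly lower. Of 10 measured oestrogen-responsive genes, 6 were at least 2-fold higher and 1 was lower, with a median of 1.83 (3.57-fold), above all 10000 random lists. Clca1 was 9.10-fold higher, Greb1, a direct oestrogen receptor target, 7.72-fold, lactoferrin, Ltf, 5.68-fold to a signal of 8118, and lipocalin 2, Lcn2, 4.51-fold. Igfbp3, an IGF-binding protein, was the member lower in the null (log2 -1.73), and the mucin Muc1 stood at 0.46, both chosen after their values were seen. Among 12 progesterone-responsive genes 1 was higher and 2 were lower, with a median of -0.29 at percentile 1.14. Alox15, a lipoxygenase, was 7.26-fold lower (4311 to 594), the Hedgehog receptor Ptch1 2.24-fold lower, Il13ra2 5.86-fold higher and follistatin, Fst, 1.81-fold higher. That list lay outside the random range in 10 of 12 settings. Its mean, -0.12, was at percentile 12.8, and with the median over probe sets its median, -0.14, was at percentile 12.2. Further, 5 oestrogen and 6 progesterone list genes also belong to other lists. Marker lists of glands, smooth muscle, macrophages and stroma, with medians of 1.26, 1.38, 0.93 and 0.72, were higher on the same array.

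Steroid receptors and their co-regulators differed little. None of 12 reached 2-fold and the median was 0.25, within the range of random lists, with Hsd11b2 1.92-fold and Hsd17b11, a steroid dehydrogenase, 1.79-fold higher, and the coactivators Ncoa2 1.59-fold and Ncoa6 1.44-fold lower. The oestrogen receptor gene Esr1, chosen after its values were seen, had probe sets at 0.45, -0.13 and 0.30. The progesterone receptor gene Pgr, also chosen afterwards, gave 0.13, 0.59 and 2.47, so its probe sets did not give 1 size. The implantation signalling list (19 measured, 2 higher, none lower, median 0.01) held Hbegf, an EGF-family ligand, 3.78-fold higher, and the LIF receptor Lifr 2.01-fold higher, with Egfr 1.81-fold and the cytokine inhibitor Socs3 1.74-fold lower.

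Wnt ligands, a theme that the labels themselves name, were not shifted as a group beyond the random range. Of 7 measured ligands 2 were higher and none lower, with a median of 0.01: Wnt7b was 2.95-fold and Wnt4 2.01-fold higher, Wnt9a 1.11-fold higher, and Wnt5a, at 4 probe sets, ranged from -1.05 to 0.02. The list of Wnt receptors and secreted antagonists (18 measured, 2 higher, 2 lower, median 0.12) held opposite extremes. Fzd4 was 17.0-fold higher, Sfrp4 1.73-fold higher, Ror2 12.6-fold lower and Fzd5, a Frizzled receptor of the uterine epithelium, 4.47-fold lower. Among 13 Wnt/beta-catenin target genes 4 were higher and 1 was lower, with a median of 0.54 at percentile 98.8. The Wnt feedback inhibitors Apcdd1 and Axin2 were 6.66-fold and 2.37-fold higher, with the 4 probe sets of Apcdd1 between 2.39 and 2.89, and Ccnd1 was 2.51-fold higher, against the lower Lgr5. The list lay outside in 10 of 12 settings: its mean, 0.32, was at percentile 83.1, and with the median over probe sets its median, 0.39, was at percentile 95.2. Markers of stroma, smooth muscle and macrophages, at 0.72, 1.38 and 0.93, were higher on the same array.

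FGF/ERK target genes were lower as a list, whereas the list of FGF ligands and receptors lay inside the random range. Of 10 target genes 2 were lower and 1 was higher, with a median of -0.41 at percentile 0.60. Beside Etv5, the ERK phosphatase gene Dusp4 was 2.74-fold and the feedback inhibitor Spry2 1.80-fold lower, while Phlda1 was 4.53-fold higher. With the floor at the 33rd or 67th percentile the median was -0.30, at percentiles 2.52 and 3.26. Mesothelial markers were lower on the same array (median -0.60), whereas those of smooth muscle, macrophages and stroma were higher (1.38, 0.93 and 0.72). None of 6 measured FGF ligands and receptors reached 2-fold and their median was -0.08: Fgf1 stood at 0.34 (further probe sets at 0.25 and -0.07), Fgf18 at -0.21, Fgfr2 at -0.12 (further probe sets at -0.56 and -0.89) and Fgfrl1 at -0.12.

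BMP targets of the Id family were among the most elevated genes, although their pathway list as a whole was split. Of 21 measured genes of the BMP and TGF-beta pathway 8 were higher and 1 was lower. Id3 was 21.6-fold, the type I receptor gene Bmpr1b 9.38-fold and Id4 8.58-fold higher, and Id1 stood at 3.46 on the log2 scale, from 648 to 7129, with the 3 Id4 probe sets between 2.86 and 3.57. Bambi and Atoh8, further genes that respond to BMP signals, were chosen after their values were seen and did not rise alike. Bambi stood at -0.29 (1827 to 1498) and Atoh8, below the floor in the control, at a bound of 0.71. The list median was only 0.20, within the random range, while the mean of 0.77 lay above it. The list was outside in 6 of 12 settings. In the Hedgehog pathway (8 measured, none higher, 1 lower, median 0.29) Ptch1 was 2.24-fold lower, while the ligand Ihh stood at 0.51, Smo at 0.30 and Gli1 at 0.28. The Notch pathway (14 measured, 2 higher, 1 lower, median 0.00) showed its target Hey1 5.88-fold higher, the ligand Jag2 2.31-fold higher, Jag1 2.67-fold lower and Notch3 1.88-fold higher. Markers of smooth muscle and stroma, at 1.38 and 0.72, were higher on the same array.

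Of 3 lists of defence genes, 1 lay outside the random range. The antimicrobial and innate defence list had 4 of 16 measured genes at least 2-fold higher and none lower, with a median of 0.64 above all 10000 random lists. Ltf (5.68-fold) and Lcn2 (4.51-fold), which the oestrogen list shares, were joined by Wfdc18 (2.62-fold) and the beta-defensin Defb1 (2.62-fold). Of chemokines and cytokines (23 measured, 5 higher, 2 lower, median 0.26) the mucosal chemokine Ccl28 was 5.14-fold, Il6 4.82-fold, Ccl8 2.42-fold and Ccl25 2.25-fold higher. That list was outside in 1 of 12 settings, with the 33rd percentile floor, where its median was 0.70 at percentile 99.97. Interferon-stimulated genes (23 measured, 1 higher, 1 lower, median 0.02) showed Psmb9, a proteasome subunit, 2.44-fold higher, the RNA sensor Ddx58 2.52-fold lower, Bst2 1.93-fold higher and Igtp 1.73-fold higher. The macrophage marker median on these arrays was 0.93.

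Of 5 lists on prostaglandins, transport, the cell surface and retinoids, 1 lay outside the random range. In the prostaglandin pathway 3 of 13 genes were lower and 2 higher, with a median of -0.29 at percentile 1.55. The PGE2 receptor gene Ptger2 was 4.95-fold lower and Alox15 7.26-fold lower, while the prostaglandin transporter Slco2a1 was 7.52-fold and the synthase Ptgds 2.80-fold higher. The prostaglandin list was outside in 9 of 12 settings. It was inside at percentile 4.66 with the 33rd percentile floor, 7.21 by the mean and 16.4 without probe sets of shared or alternative sequence. Markers of mesothelium were lower on the same array (median -0.60) and those of smooth muscle, macrophages and stroma higher (1.38, 0.93 and 0.72). Ion and water channels (16 measured, 2 higher, 4 lower, median 0.02, mean -0.11) held Sgk1, a kinase that activates the epithelial sodium channel, 5.17-fold higher, and Slc26a6, the carbonic anhydrase Car12 (2.62-fold) and the water channel Aqp4 (log2 -1.32) lower. Mucins and glycocalyx genes (14 measured, none higher, 2 lower, median 0.01, mean -0.04) included the fucosyltransferase Fut4 2.48-fold lower, with Galnt3 1.83-fold, Podxl 1.76-fold and Muc20 1.61-fold higher. Of 29 genes of cell junctions and apical polarity 2 were higher and none lower, with a median of 0.09: beside Cldn1, the desmosomal cadherin Dsc2 was 2.38-fold higher, while Cldn10 was 1.63-fold higher and Cldn8 1.66-fold lower. Retinoid metabolism (13 measured, 3 higher, none lower, median 0.20) held Crabp2 and the retinal dehydrogenase Aldh1a1 (2.88-fold) higher, with Dhrs3 1.78-fold and Rdh10 1.51-fold lower.

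**Figure D2:**
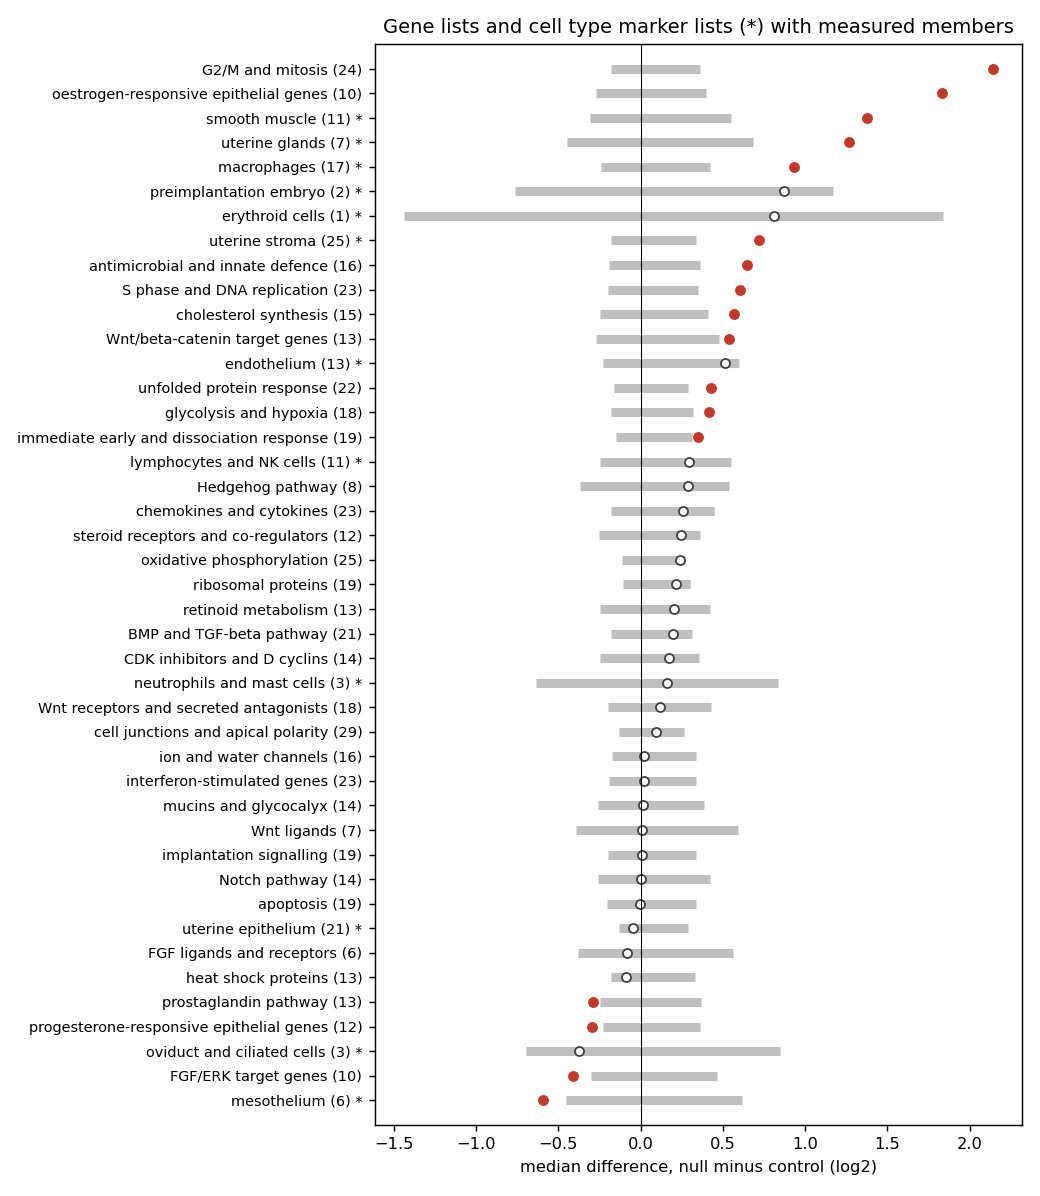
Median log2 difference (null minus control, x axis) of each gene list and, with an asterisk, each cell type marker list, with the number of measured members in parentheses and 1 array per genotype; grey bars span the central 95% of 10000 random lists matched on signal. Red points mark the 17 lists outside their bar, from G2/M and mitosis at 2.14 to mesothelium at -0.60.

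Of 5 lists of metabolism and protein synthesis or folding, 3 lay above the random range. Cholesterol synthesis had 5 of 15 genes at least 2-fold higher and none lower, with a median of 0.57 at percentile 99.8, led by squalene epoxidase, Sqle (5.37-fold), Fdps (2.73-fold), Insig1 (2.56-fold) and Hmgcs1 (2.35-fold, probe sets from 0.22 to 1.24). Glycolysis and hypoxia genes (18 measured, 2 higher, none lower) had a median of 0.41 at percentile 99.7, with Pdk1 2.12-fold, Pgk1 2.01-fold, Pfkp 1.94-fold and the glucose transporter Slc2a1 1.72-fold higher, and their mean, 0.31, was inside the random range. The unfolded protein response (22 measured, 1 higher, 1 lower) had a median of 0.43 at percentile 99.9, with Sdf2l1 2.48-fold, Atf3 1.94-fold and Pdia6 1.93-fold higher and the chaperone Hsp90b1 2.43-fold lower. Its mean of 0.31 also lay inside the random range. None of 25 oxidative phosphorylation genes (median 0.24) and none of 19 ribosomal protein genes (median 0.21) reached 2-fold, and both lists lay inside the random range, at percentiles 94.4 and 82.6. Their most distant members were Ndufb8 at -0.72 and Sdhb at 0.70, Atp5c1 at 0.52 and Cox5a at 0.44, and, among ribosomal proteins, Rps9 at 0.44, Rpl8 at 0.40, Rplp0 at 0.36 and Rps19 at 0.31. Marker lists of smooth muscle, macrophages and stroma were higher on the same array, with medians of 1.38, 0.93 and 0.72.

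Of 3 lists of stress and survival genes, 1 lay outside the random range. Immediate early genes, which tissue dissociation can induce, had 1 of 19 members above 2-fold, Klf6 (2.42-fold), with Atf3 1.94-fold, Nr4a1 1.62-fold and Egr2 1.52-fold higher. Their median of 0.35 lay at percentile 99.1, and the list was outside the random range in all 12 settings. With spike-in scaling the median was only 0.07, still at percentile 99.2, because that scaling moves the random lists as well. Macrophage and stromal markers on the same array had medians of 0.93 and 0.72. None of 13 heat shock protein genes reached 2-fold (median -0.09): Hspa1a stood at -0.78, Hsp90aa1 at -0.49, Hspa1b at -0.30 and Hspb8 at -0.28. In the apoptosis list (19 measured, 2 higher, none lower, median -0.005, mean 0.23) Apaf1, the apoptosome scaffold, was 5.74-fold higher and the survival factor Bcl2 2.45-fold higher, with Bak1 1.88-fold and Bbc3 1.67-fold higher.

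The median of epithelial markers was close to 0, while markers of several other cell types were higher in the null. The uterine epithelium list (21 measured, none higher, 1 lower) had a median of -0.04, with Krt19 1.47-fold higher, the splicing regulator Esrp2 2.10-fold lower, Prom1 1.69-fold lower and Tmprss2 1.69-fold higher, although the 4 Tmprss2 probe sets ran from -0.45 to 0.76. Gland markers (7 measured, 4 higher, 1 lower) had a median of 1.26 at percentile 99.9: Cxcl15 was 4.61-fold, Aldh1a1 2.88-fold and the gland transcription factor Foxa2 2.40-fold higher, Fxyd4 stood at 0.22 and Spink1 was lower. Their mean, 0.68, lay inside the random range. Of 25 stromal markers 8 were higher and none lower, with a median of 0.72 above all 10000 random lists, led by Col5a2 (13.1-fold), Col6a3 (2.98-fold), Col5a1 (2.70-fold) and Col6a2 (2.45-fold). Decorin, Dcn, the brightest of the list, stood at -0.12 (4213 in the control, 3877 in the null) and Lum at 0.01 (520 and 524), 2 members chosen after their values were seen. The epithelial marker Cdh1, also chosen afterwards, read 3987 and 3124. Signals of different probe sets do not give amounts that can be compared, but neither sample is shown to be pure epithelium. Smooth muscle markers (11 measured, 8 higher, none lower) had a median of 1.38 above all 10000 random lists, with Pcp4 4.35-fold, Acta2 3.66-fold, Tagln 3.38-fold and Tpm2 2.62-fold higher. Macrophage markers (17 measured, 7 higher, none lower) had a median of 0.93, again above all random lists, with the MHC class II genes H2-Aa (2.70-fold) and H2-Ab1 (log2 1.32), their partner Cd74 (4.40-fold) and the complement gene C1qc (2.30-fold) highest.

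The remaining marker lists differed less, pointed the other way or were thinly measured. Endothelial markers (13 measured, 1 higher, none lower, median 0.51) lay inside the random range, but outside it in 2 of 12 settings, with medians from 0.16 to 0.61 over the settings, and held Emcn 2.04-fold, Kdr 1.81-fold, Eng 1.77-fold and Plvap 1.75-fold higher. Lymphocyte and NK cell markers (11 measured, 2 higher, none lower, median 0.29) held the granzymes Gzmb 3.53-fold higher and Gzma 1.32-fold lower, Klrd1 1.62-fold lower and Nkg7 1.30-fold higher. Mesothelial markers went the other way, with a median of -0.60 at percentile 0.71 and none of 6 reaching 2-fold: Wt1 stood at -0.72, Bnc1 at -0.70, Msln at -0.62 and Lrrn4 at -0.57. Neutrophil and mast cell markers (3 measured, none higher, 1 lower, median 0.16, mean -0.23) included Kit 2.15-fold lower, and the only measured erythroid marker, Alas2, was 1.76-fold higher (0.81). Oviduct and ciliated cell markers (3 measured, none past 2-fold) had a median of -0.37, with Ovgp1 at 0.89, Cfap126 at -0.86 and Pax8 at -0.37. That median has no settled direction: it was 0.89, above the random range, with the 33rd percentile floor and -0.86, below it, with the median over probe sets. Of 2 measured preimplantation embryo markers (median 0.87) 1 was higher, Elf5 (2.77-fold).

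**Figure D3:**
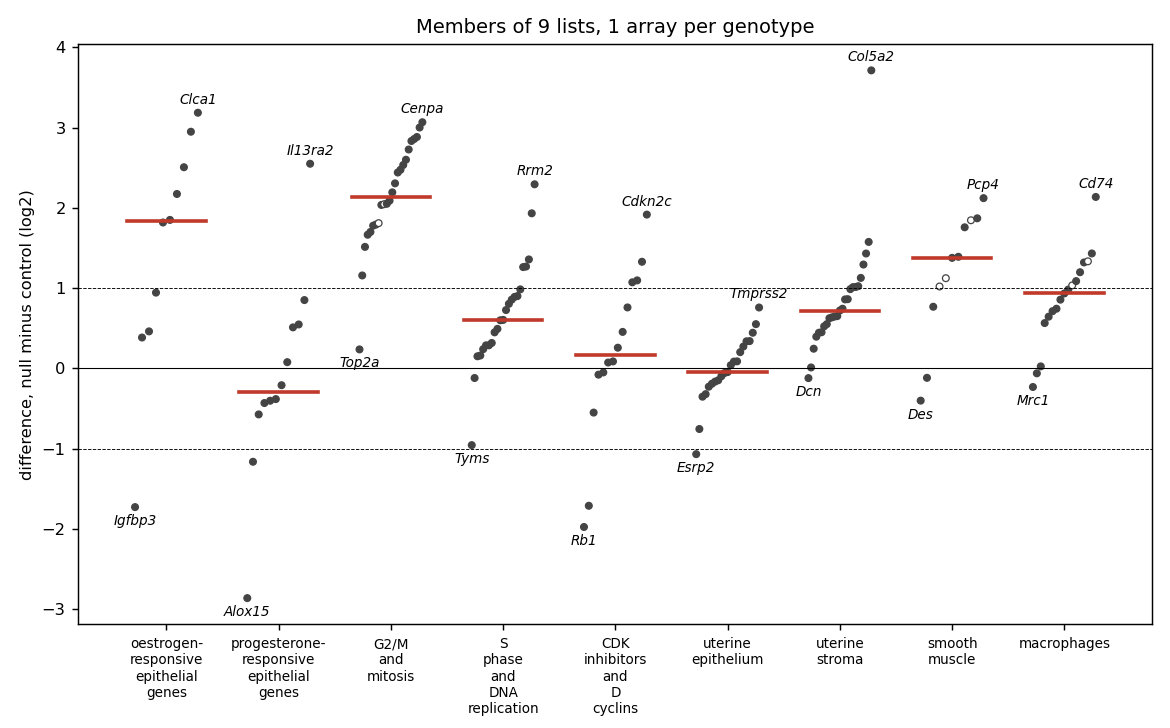
Log2 difference (null minus control, y axis) of each measured member of 9 lists, with 1 array per genotype; points are genes, open where 1 array was below the floor, red bars are list medians and dashed lines mark 2-fold. The medians are 2.14 for G2/M and mitosis, 1.83 for oestrogen-responsive genes and -0.04 for uterine epithelium.

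In all, 17 of the 43 lists had medians outside the central 95% of random lists, 13 above and 4 below. On average 2.15 would lie outside if the members of a list varied independently, as those of random lists do. Members of a real list can vary together, so the random ranges may be too narrow. Some genes (31) belong to more than 1 list. For lists inside the range no direction is given.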

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

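The comparison of hybridization controls, the look at probe sets without a gene name and the comparison by gene span were chosen only after the values were seen; the tests of signal and of nuclear RNA were fixed before their own results were known. Spike-in transcripts bioC, bioD and cre, which are added to the hybridization mix and lie outside the comparison of genes, were brighter on the null array at all 12 of their probe sets, with a median log2 difference of 0.27. The poly-A controls, added to the RNA before labelling, had a median of 0.15 over 12 probe sets.

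Probe sets without a single gene name, which the comparison of genes leaves out, also carried signal. Of 2468 that were above the floor on both arrays, 73 (2.96%) were at least 2-fold higher in the null and 454 (18.4%) at least 2-fold lower. Named probe sets (18185) gave 5.70% and 6.38%, so the unnamed ones leaned towards the control.

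Lower signals of the unnamed probe sets are argued against as the cause: among named probe sets matched on mean signal 6.47% were at least 2-fold lower, far under the 95% Wilson interval of the unnamed share, 16.92% to 19.97%. Some such probe sets may lie in introns or unspliced transcripts, but their positions were not examined, and the group also holds probe sets that name several genes. Less nuclear or unspliced RNA in the null sample may be part of the pattern. A list of 15 nuclear-retained non-coding RNAs was fixed beforehand, without Xist, whose value had been seen. Of its 9 measured members 8 were lower, with a median of -0.67 (95% bootstrap interval -0.99 to -0.08). That interval resamples members on this pair of arrays and holds no spread between arrays or animals. Among the lower members were Kcnq1ot1 at -1.76, Malat1 at -0.93 and Neat1 at -0.67, with Airn at 0.50 as the exception. With genes in 5 groups from the shortest to the longest genomic span, the share at least 2-fold lower was 3.65%, 3.22%, 3.35%, 5.93% and 7.51% and the median went from 0.16 to 0.01, but the share at least 2-fold higher was also 8.28% in the shortest and 9.27% in the longest. How the cells were lysed and an effect of genotype on these RNAs both stay open, since there was 1 array per genotype.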

How the results depend on the processing

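The scaling to hybridization controls was chosen only after the result was seen; the other alternatives were planned. The count of higher genes, 902, was 2040 at 1.5-fold, 346 at 3-fold, 495 with the 67th percentile floor and 593 with spike-in scaling. The count of lower genes, 554, was 1405, 176, 365 and 1001 in the same order. Fold thresholds and a higher floor move counts by construction; the spike-in scaling lowered differences above the floor by 0.27, so that higher genes were 37.2% of the total in place of 62.0%. Under the other 7 alternatives higher genes numbered 774 to 1341 and lower genes 472 to 793. The Msx1 difference, -6.36, was -5.58 with the 67th percentile floor, -5.90 with a pseudocount of 16 and -5.88 without probe sets of shared or alternative sequence. That of Msx2, -1.43, was -1.01 with the pseudocount and had no value with the 67th percentile floor, where both arrays were below it. Raised floors and pseudocounts shrink differences of dim probe sets by construction. A shift of a whole array moves a list and its random lists alike, so percentiles hardly change with it by construction. Lists outside the random range numbered 12 to 19 against 17, and 10 lists were outside in all 12 settings: oestrogen-responsive genes, S phase, G2/M, antimicrobial genes, cholesterol synthesis, immediate early genes, stroma, smooth muscle, macrophages and mesothelium. Of 295 values of named genes under alternatives, 244 stayed within the probe set standard deviation of 0.38, 51 moved by more and 0 reversed. These genes were picked for large differences on the same arrays, so a reversal was unlikely from the outset and its absence does not support their directions. Of 471 list medians, 457 stayed within it and 14 moved by more; none of the lists outside the random range reversed. Several medians inside it took either sign, and that of oviduct and ciliated cells ran from -0.86 to 0.89. No paired analysis was possible because the labels give no replicate numbers and there was 1 array per genotype, which also ruled out leaving arrays out. Signals near the floor of 21.1 limit the folds of dim genes.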

Other observations

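All gene families below, and the tests of the cell division and marker patterns, were chosen only after the result was seen, and the families were not placed among random lists. Of 20 beta-defensins with a probe set 4 were measured, and all 4 were at least 2-fold higher in the null. Defb2, at least 13.8-fold higher, Defb3 and Defb6 were above the floor on the null array only, so their selection as measured favours that direction, while Defb1 was above it on both. Of 21 immunoglobulin chain genes, products of antibody-secreting cells, 8 were measured and 7 were at least 2-fold higher, but 4 of these were above the floor on the null array only, which again favours that direction; on both arrays it was 3 of 4. Igha, the IgA heavy chain, was 11.2-fold higher, from 595 to 6693, with 3 probe sets between 3.40 and 3.62, while Ighm, the IgM heavy chain, stood at 0.35. Of 42 collagens with a probe set 25 were measured, of which 10 were higher and 1 was lower. The basement membrane chains Col4a1 and Col4a2 were 3.77-fold and 2.87-fold higher. The type VI chain gene Col6a4 was 6.28-fold higher from a control signal of 24.0, close to the floor. Col20a1, the lower one, had 3 probe sets from -1.09 to 0.72, and no collagen was at least 2-fold lower with quantile or loess scaling. All 4 Id genes were at least 2-fold higher by their brightest probe set, Id2 by 3.04-fold, although its 3 probe sets ran from 0.32 to 1.60. With spike-in scaling 6 immunoglobulin chains and 7 collagens were at least 2-fold higher.

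Circadian clock genes went both ways, with 4 of 16 at least 2-fold lower, 2 higher and 10 between (median -0.49). Rora, a nuclear receptor that activates Arntl, was 6.85-fold lower with 5 probe sets between -3.41 and -2.28, Clock 4.17-fold, Per2 3.25-fold and Npas2 3.08-fold lower. With spike-in scaling 7 clock genes were lower and 1 was higher. Cry1 was 2.42-fold and Bhlhe40 2.02-fold higher, while Arntl stood at -0.10 and Per1 at -0.01. Glutathione S-transferases split, with 3 of 18 higher, among them Gstm7 (3.54-fold), and 2 lower, among them Gsta4 (3.47-fold).

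The higher G2/M genes were weighed against 3 technical sources. More cells of other types in the null sample stay open: the G2/M median exceeded that of smooth muscle, the highest of 7 other marker lists, by 0.76 (95% bootstrap interval 0.22 to 1.51), but set against immunoglobulin chain genes, products of antibody-secreting cells, it differed by -0.74 (-1.59 to 1.24). Scalings of the size tried are argued against by a lowest median of 1.88 over the deposited and 4 other scalings. These moved the median difference of all genes only to between -0.19 and 0.11, so they could hardly have undone a list median of 2.14. Noise of low signals is argued against by a median of 2.44 (1.51 to 2.83) in the 9 members above a signal of 72.7 on both arrays. All these intervals resample the genes of a list on this pair of arrays. They hold no spread between arrays or animals, and genes of a list can vary together. More dividing cells in the null epithelium is a hypothesis that may be followed up. Division of carried-over cells and a difference between the sampled mice stay open and untested with 1 array per genotype.

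The higher stromal, smooth muscle and macrophage markers were weighed as a matter of cell makeup. A lower share of epithelial cells would raise all other cell types alike only if these kept their proportions to each other. The highest and lowest of 7 other marker lists, smooth muscle and mesothelium, differed by 1.97 (95% bootstrap interval over list members 1.34 to 2.46). Both were picked as the extremes of these same data, which widens the gap, so a lower epithelial share stays open. Whether more stromal cells were carried over stays open. The 8 stromal markers brightest on the control array had a median of 0.60, near the lower end of the interval of the whole list. That interval was 0.55 to 1.01 from 100000 resamples, and its lower end ran from 0.55 to 0.63 over 20 runs of 2000. The 8 markers are part of that list, so the comparison was unlikely to go against carry-over and does not decide it. Dcn at -0.12 and Lum at 0.01 do not share the shift of the stromal list, and Col5a2 at 3.71 far exceeds it. All 25 measured stromal markers were above the floor on both arrays, and 4 of the list belong to other lists. Expression of these genes altered by the genotype, in stroma or epithelium, stays open and was not tested.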
